A study of Mus musculus with 23 samples.

How the data were processed

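Each of the 23 samples was 1 mouse cell hybridized to 1 Affymetrix mouse expression array after amplification of its RNA, and the groups were taken from the labels: 5 fibroTIPeR, 3 fibroControl, 3 fibroblast, 4 cardiomyocyte, 6 astroTIPeR and 2 astroControl cells. The labels call the cells of a group replicates without naming a culture or an animal, so every test treats cells as the unit and its p-value does not extend to cultures or animals. The labels name lipid transfection of poly-A RNA and single-cell amplification, and the number of arrays limits the precision.

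The deposited table held log2 expression values for 45101 probe sets, as judged from their range, and the summarization and normalization that the authors used to make them are not given in the sources used here. The columns fell in 2 sets. The 15 arrays of fibroblasts and cardiomyocytes had medians of 5.05 to 5.58 and minima of 1.35 to 1.71, and the 8 arrays of astrocytes had medians of 4.28 to 4.56 and minima of 0.391 to 0.784; whether the sets were normalized separately, and how each was scaled or centred, is not given in the sources used here. Correlations between arrays ran from 0.546 to 0.918, and no pair of arrays held identical values. It was decided before the data were examined that quantile normalization of all columns would be used if the column medians differed by more than 1 log2 unit; they differed by 1.29, so the values were quantile normalized. Levels that cross the 2 sets rest on this step. Detection calls are not given in the sources used here and no background level was set. No pseudocount was needed, since the values were on a log2 scale.

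The 64 control probe sets were left out of the tests. Of the others, 34945 carried 1 gene symbol, 932 carried several and 9160 were not listed in the annotation; the latter kinds were not used. Gene IDs of 34741 probe sets matched the reference gene table, and no symbol changed. Where a gene had more than 1 probe set (9010 genes), the one with the highest mean over all samples was used, which left 18193 genes; for the genes named for the largest changes of a comparison the text says where another probe set differed in sign, and for genes past the threshold named through a list where the mean of the probe sets did.

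Genes were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), using lmFit with a mean for each of the 6 groups over all 23 cells and eBayes with a trend in mean expression, two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. The 7 comparisons and the difference of the transfer effect between recipient types were tested this way. Gene lists were tested with camera of limma at a correlation between genes of 0.01, and again with an estimated correlation and with fry, with adjustment over the 17 lists of a comparison. A standard error over genes describes the spread of list members, which are not independent. Positions and correlations were tested with two-sided exact permutation tests of the cells. Intervals are 95% intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

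The comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The lists covered the cardiac sarcomere, cardiac calcium handling and excitability, cardiac transcription factors, muscle energy metabolism and cardiac hormones, skeletal muscle, fibroblast and extracellular matrix, smooth muscle and myofibroblast, astrocyte, neuron, oligodendrocyte lineage, endothelial, macrophage and microglia, cell cycle, interferon and foreign RNA response, stress and unfolded protein response, pluripotency and housekeeping genes. For each comparison the rule named up to 8 genes per direction with the largest change among those past the threshold whose groups did not overlap, or the 5 genes with the smallest p where none passed. For each list it named up to 4 members past the threshold with the largest change, or the 2 with the smallest p, and in every group a fixed set of cardiac, fibroblast and astrocyte markers.

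Alternatives were the values as deposited, median centring, genes above the median level only, the mean of all probe sets of a gene, every probe set, eBayes without trend or with robust = TRUE, arrayWeights, a fit of the compared groups alone, a minimum change of 2-fold, 50 or 500 genes per direction for the position, the fixed lists as its axis, Spearman correlation, the replicate number as a term, and each cell left out in turn. The 18S level as a covariate, quantile normalization within each array set, and fits with fibroTIPeR 1 to 3 or fibroTIPeR 4 and 5 alone were added after seeing the data.

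The pipeline was tested on simulated data with the group sizes of these arrays, in which 200 of 18193 genes were changed. Genes were drawn independently, each with 1 spread estimated from these arrays and shared by all groups. With fewer changed genes the adjustment would be stricter and the shares given here lower. In fibroTIPeR against fibroControl, 19.4% of genes changed by 2 log2 units, 77.6% of those changed by 4 and 97.0% of those changed by 6 passed, with 5 false calls. In cardiomyocyte against fibroblast the shares were 20.9%, 73.1% and 97.0% with 9 false calls, in fibroControl against fibroblast 10.4%, 70.1% and 89.4% with 1, and in astroTIPeR against astroControl 13.4%, 73.1% and 100% with 4. A simulated shift of 1 list in fibroTIPeR against fibroControl gave it an adjusted p of 4.11e-36 with camera, and 0 of the 16 other lists passed. This was 1 draw with independent genes, so it does not show how often lists of correlated genes pass falsely.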

Results

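Expression was measured on Affymetrix mouse arrays in 23 single cells, each drawn into a glass micropipette and its RNA amplified before labelling. The cells formed 6 groups. Untreated fibroblasts (3 cells) and cardiomyocytes (4 cells) were the reference types. FibroTIPeR cells (5) were fibroblasts, and astroTIPeR cells (6) astrocytes, that had been given poly-A RNA of cardiomyocytes with a lipid reagent, a transfer known as transcriptome-induced phenotype remodeling (TIPeR). FibroControl cells (3) were fibroblasts given fibroblast RNA, and astroControl cells (2) were mock-transfected astrocytes. Every sample was 1 cell, so n counts cells. The labels do not say that the cells came from separate cultures or animals, so the p-values measure only the spread between these cells, which may be technical in part, and the number of arrays limits the precision. Levels are given on a log2 scale after quantile normalization, where the median of all genes was 5.71 and the 90th percentile 10.94, and differences are in log2 units. No background level or detection call was used here, so the sizes of differences from levels well below that median, and their order, are not exact.

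The libraries differed in ways that moved with some of the groups. The 3 control probe sets for 18S ribosomal RNA, which poly-A priming should largely leave out, averaged 11.6 ± 0.428 (SD, n = 3) in fibroControl cells, 7.45 ± 0.533 (n = 3) in fibroblasts and 7.48 ± 0.593 (n = 4) in cardiomyocytes. FibroTIPeR cells lay at both levels, with 12.4, 11.03 and 13.5 in replicates 1 to 3 and 7.80 and 7.88 in replicates 4 and 5. AstroTIPeR cells averaged 8.73 ± 0.678 (n = 6) and astroControl cells 8.63 ± 0.651 (n = 2). Probe sets for the B2 repeat, a short interspersed element of the mouse genome, averaged 11.7 ± 0.737 in fibroControl, 11.1 ± 2.52 in fibroTIPeR, 8.34 ± 2.35 in fibroblast and 7.13 ± 0.533 in cardiomyocyte cells. Fibroblast 3 stood apart from the other two fibroblasts, with 11.02 for B2. The difference between the 3' and 5' control probe sets of Gapdh, which grows as RNA is shorter at its 5' end, averaged 4.22 ± 1.12 in fibroTIPeR, 5.37 ± 0.53 in fibroControl, 5.28 ± 1.02 in fibroblast, 4.89 ± 1.20 in cardiomyocyte, 4.03 ± 0.80 in astroTIPeR and 2.07 ± 0.79 in astroControl cells. The mean correlation of a cell with the others of its group was 0.773 in fibroTIPeR, 0.812 in fibroControl, 0.835 in fibroblast, 0.854 in cardiomyocyte, 0.878 in astroTIPeR and 0.754 in astroControl cells. The arrays of fibroblasts and cardiomyocytes and those of astrocytes also formed 2 sets with different value ranges, so that any level set across them compares array set and cell type together.

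**Figure D1:**
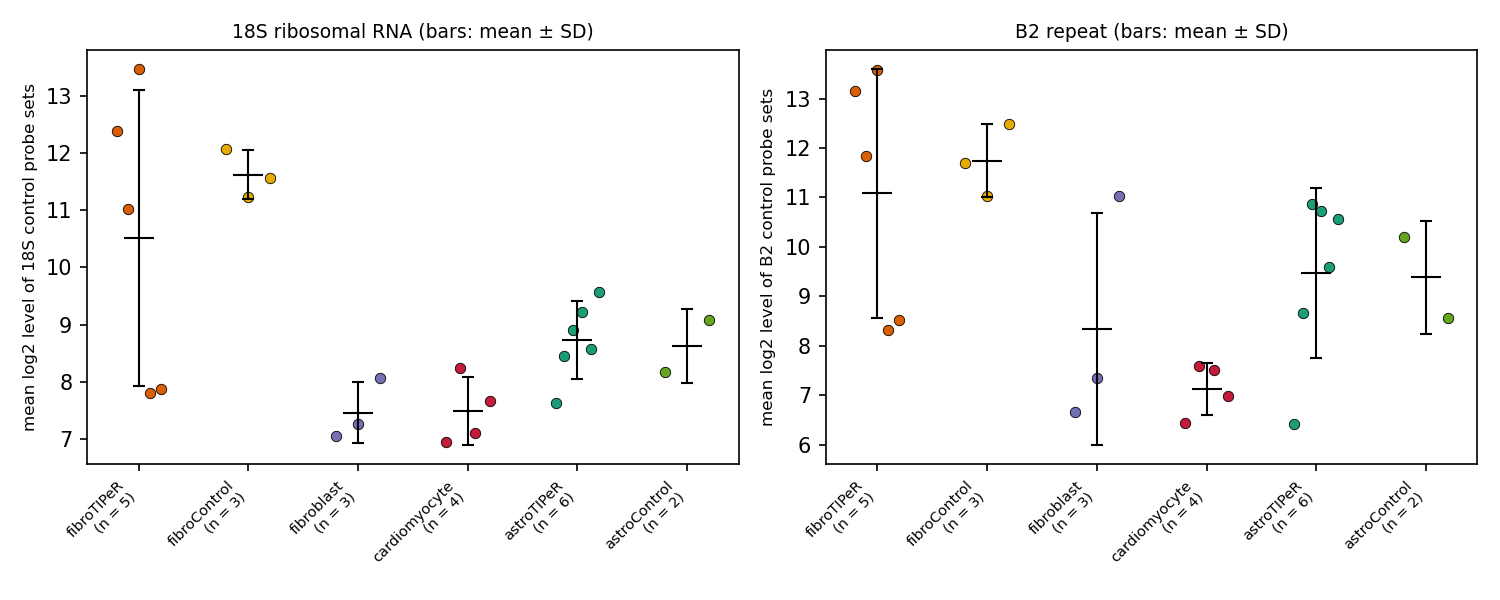
Mean log2 level of the 18S ribosomal RNA control probe sets (first panel) and of the B2 repeat control probe sets (second panel) in every cell, by group; dots are cells and bars the mean ± SD. FibroTIPeR cells 4 and 5 lie at 7.80 and 7.88 for 18S, with the fibroblasts and cardiomyocytes, and the other 3 fibroTIPeR cells lie between 11.03 and 13.5, with the fibroControl cells.

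Cardiomyocytes and untreated fibroblasts were compared first, to define the donor and recipient programs that the transfer was meant to bridge. Cardiomyocytes were higher in the sarcomere and energy metabolism lists. Cardiac troponin I (Tnni3) stood at 11.96 ± 0.98 (SD, n = 4) against 4.76 ± 0.66 in fibroblasts (n = 3), a difference of 7.20 (SE 0.82, adjusted p = 2.64e-05). The ventricular myosin light chain Myl2 rose by 5.67 (SE 0.68, adjusted p = 4.62e-05), alpha myosin heavy chain Myh6 by 4.30 (SE 0.74, adjusted p = 0.00584), and Plin5, which coats lipid droplets in oxidative tissue, by 5.97 (SE 0.57, adjusted p = 1.46e-06). Vimentin (Vim), the intermediate filament protein of mesenchymal cells, was at 14.85 ± 0.46 in fibroblasts and 5.81 ± 3.77 in cardiomyocytes, a difference of -9.04 (SE 1.14, adjusted p = 8.09e-05), and the actin-binding proteins Actn1 (-6.56), Tpm3 (-6.04), Lasp1 (-5.96) and Cald1 (-5.95), the tubulin Tuba1a (-6.66), the dynein light chain Dynll1 (-5.91) and the mitochondrial carrier Slc25a24 (-5.88) fell as well.

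Of 25 measured members of the cardiac sarcomere list, 7 rose, none fell and 18 did not pass, among the 7 Tnni3, the Z-disc protein Myoz2 (5.76), Myl2 and myosin-binding protein C (Mybpc3, 4.94). Adjusted over the list alone, 12 members rose and 1 fell, and the list mean was 1.85 (SE over genes 0.52, adjusted p = 1.05e-09). In the list for muscle energy metabolism and cardiac hormones, 4 of 21 members rose, namely lipoprotein lipase (Lpl, 5.34), mitochondrial creatine kinase (Ckmt2, 3.14), the muscle form of a cytochrome oxidase subunit (Cox7a1, 2.93) and myoglobin (Mb, 2.85), and 17 did not pass. There the mean was 1.14 (SE 0.35, adjusted p = 7.02e-05), with 5 higher adjusted over the list alone. Of 26 calcium handling and excitability genes, the calcium pump of the sarcoplasmic reticulum Atp2a2 rose (5.52, adjusted p = 0.0358) and 25 did not pass, 4 rose adjusted over the list alone, and the list mean was 0.72 (adjusted p = 0.0387, and adjusted p = 0.117 with an estimated correlation). The fibroblast and extracellular matrix list fell by 1.40 on average (SE 0.40, adjusted p = 6.55e-05), with Vim and the calcium-binding protein S100a4 (-5.03, adjusted p = 0.00268) lower and 29 of 31 members not passing (4 lower adjusted over the list alone). In this list the fibroblasts spread widely, with collagen III (Col3a1) at 9.24, 4.73 and 12.53 in fibroblasts 1 to 3. Smooth muscle and myofibroblast genes fell by 1.63 (adjusted p = 0.0169, and adjusted p = 0.0611 with an estimated correlation), where Cald1 passed and 9 did not (1 lower adjusted over the list alone). None of 13 housekeeping genes passed over all genes, 7 were lower adjusted over the list alone, and the list mean was -1.63 (SE 0.55, adjusted p = 0.000220, and adjusted p = 0.273 with an estimated correlation); beta-actin (Actb) was at 6.54 in cardiomyocytes and 10.70 in fibroblasts (adjusted p = 0.0784). The mean 18S level was alike in both groups of cells, whereas B2 was higher in fibroblast 3.

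The other 11 lists did not pass between cardiomyocytes and fibroblasts. Mean differences were 0.37 for cardiac transcription factors (adjusted p = 0.254), -0.36 for skeletal muscle (0.218), 0.030 for astrocyte (0.844), 0.38 for neuron (0.218), 0.11 for oligodendrocyte lineage (0.967), 0.10 for endothelial (0.987), 0.11 for macrophage and microglia (0.463), -0.040 for cell cycle (0.506), -0.050 for interferon and foreign RNA response (0.904), -0.24 for stress and unfolded protein response (0.550) and -0.14 for pluripotency genes (0.663). The lysosomal gene Laptm5, in the macrophage list, was 0.33 higher (adjusted p = 0.0442), a sign that turned to -0.14 with the mean of its probe sets. Several genes often used as cardiac markers did not pass, among them cardiac troponin T (Tnnt2, -0.46, with fibroblast 3 at 11.28 and cardiomyocytes at 7.99 ± 0.42), cardiac actin (Actc1, 3.03, adjusted p = 0.169), the ryanodine receptor (Ryr2, 3.11, adjusted p = 0.134), atrial natriuretic peptide (Nppa, -0.89), Gata4 (0.78) and Nkx2-5 (2.0). Collagen I (Col1a1, -1.19) and Col3a1 (-4.02) did not pass either.

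In all, 41 of 18193 genes passed between cardiomyocytes and fibroblasts with limma, 18 higher and 23 lower. In all 41 the groups did not overlap (5.71% of unselected genes would do so by chance). Here and below, genes past the threshold were selected for a difference, which favours groups without overlap. The chance share of unselected genes is therefore no test of them. Leaving out fibroblast 3 gave 11 genes, cardiomyocyte 1 gave 26, cardiomyocyte 3 gave 20 and cardiomyocyte 4 gave 26. Of 21 named genes that passed, 7 did so without each cell in turn: Actn1, Cald1, Myl2, Plin5, Tnni3, Tpm3 and Vim. The calcium list did not pass without fibroblast 1 (adjusted p = 0.0992), fibroblast 2 (0.0634) or cardiomyocytes 2 (0.0601), 3 (0.110) or 4 (0.0607), nor the smooth muscle list without fibroblast 3 (0.103). Another probe set of Plin5, Lpl, Actn1, Tpm3, Lasp1 and Dynll1 differed in sign from the one reported, in Actn1 for 2 of 3 probe sets and in Lasp1 for 6 of 9.

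**Figure D2:**
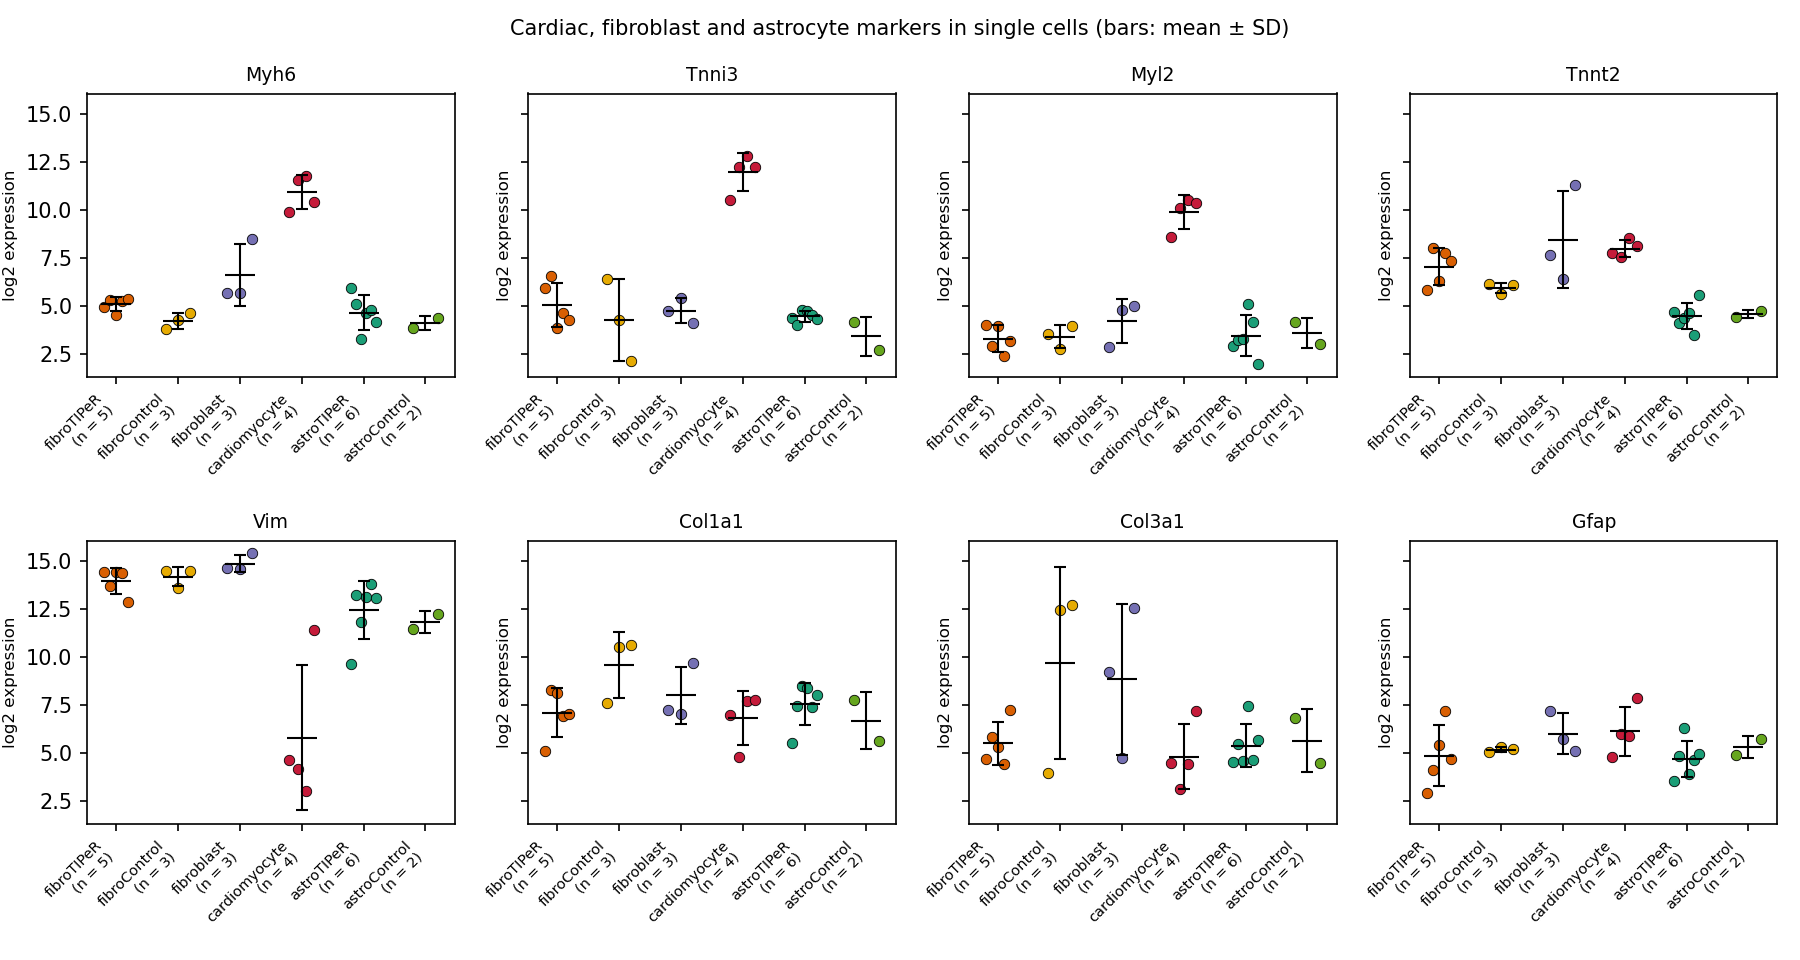
Log2 expression (vertical axis) of 8 marker genes, Myh6, Tnni3, Myl2, Tnnt2, Vim, Col1a1, Col3a1 and Gfap, in every cell of the 6 groups; dots are cells and bars the mean ± SD. Mean Tnni3 was 11.96 in cardiomyocytes and 5.05 in fibroTIPeR cells, and mean Vim was 13.96 in fibroTIPeR and 5.81 in cardiomyocyte cells.

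FibroTIPeR and fibroControl cells were compared to ask what RNA of cardiomyocytes did to fibroblasts beyond RNA of fibroblasts. A single gene passed. Corneodesmosin (Cdsn), an adhesion protein of cornified skin, was at 3.83 ± 0.87 (SD, n = 5) in fibroTIPeR and 7.83 ± 0.67 (n = 3) in fibroControl cells, a difference of -4.00 (SE 0.61, adjusted p = 0.0101), and it stood at 4.74 ± 0.69 in untreated fibroblasts. No cardiac gene passed. Atp2a2 was at 8.71 ± 2.0 against 4.54 ± 0.69 (difference 4.17, SE 1.11, adjusted p = 0.315), Myh6 at 5.09 ± 0.36 against 4.24 ± 0.41 (difference 0.86, 95% interval -0.59 to 2.30) and Tnnt2 at 7.05 ± 0.95 against 5.96 ± 0.27 (difference 1.09, interval -0.60 to 2.78). For comparison, Myh6 was 4.30 higher in cardiomyocytes than in fibroblasts, above that interval.

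The fibroblast and extracellular matrix list fell by 1.02 on average (SE over genes 0.28, adjusted p = 0.00350, and adjusted p = 0.287 with an estimated correlation). None of its 31 members passed over all genes, 3 were lower adjusted over the list alone, and 6 had positive differences. Type VI collagen (Col6a3) was at 4.93 ± 1.52 against 9.33 ± 1.79 (adjusted p = 0.0840), the matrix metalloproteinase Mmp2 at 6.50 ± 2.03 against 10.91 ± 2.68 (adjusted p = 0.212) and Col3a1 at 5.51 ± 1.10 against 9.69 ± 4.97. FibroControl cells 2 and 3 held the high values of Col3a1, 12.43 and 12.68, and fibroControl 1 the low one, 3.95. The list did not pass without fibroControl 2 (adjusted p = 0.161) or fibroControl 3 (adjusted p = 0.277). Its mean level was 8.02 ± 0.14 in fibroTIPeR, 9.04 ± 0.95 in fibroControl and 8.17 ± 0.92 in fibroblast cells.

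The cardiac lists did not pass between fibroTIPeR and fibroControl cells. Mean differences were 0.21 for the sarcomere (adjusted p = 0.757), 0.49 for calcium handling (0.307, with 1 member higher adjusted over the list alone, Atp2a2 having the smallest p), 0.051 for cardiac transcription factors (0.935) and -0.091 for energy metabolism and hormones (0.922). Among the transcription factors, Mef2c differed by 1.87 (adjusted p = 0.730), Tbx5 by 1.30, Hand2 by -0.34, Gata4 by -1.04 and Nkx2-5 by -0.12. Genes of the interferon and foreign RNA response, which cells can switch on when RNA enters them, had a mean difference of -0.045 (adjusted p = 0.935), with Ifit1 at 3.88 against 5.89. Stress genes had a mean difference of -0.28 (adjusted p = 0.549, 2 lower adjusted over the list alone), with the heat shock gene Hspa1a at 7.12 against 10.64. Vim differed by -0.21 and the astrocyte filament Gfap by -0.31.

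With limma, 1 of 18193 genes passed and 1204 had an unadjusted p under 0.05, against 909.65 expected by chance. Cdsn did not overlap between the groups (3.57% of unselected genes would do so by chance), but it did not pass without fibroControl 3. Leaving out other cells gave 17 genes (without fibroControl 1), 5 (fibroControl 2), 3 (fibroTIPeR 1), 7 (fibroTIPeR 2), 4 (fibroTIPeR 3) and 2 (fibroTIPeR 5). With fibroTIPeR 4 and 5 alone 161 genes passed, 70 higher and 91 lower, and with fibroTIPeR 1 to 3 alone none. In simulated data of this comparison, 77.6% of 67 genes changed by 4 log2 units passed, and 19.4% of 67 genes changed by 2 units.

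FibroTIPeR cells were also compared with untreated fibroblasts, which holds the effect of transfection and of the donor RNA together. Ferritin heavy chain (Fth1), which stores iron, was at 10.49 ± 2.17 (SD, n = 5) against 4.55 ± 1.18 (n = 3), a rise of 5.94 (SE 0.93, adjusted p = 0.0171). The replication factor C subunit Rfc3 fell by 5.66 (SE 1.10, adjusted p = 0.0464), the ciliary gene Lca5 by 5.03, the NF-kappa-B regulator Nfkbiz by 4.58 and the calcium-binding protein S100g by 4.46. Gm7854 (-3.98), the potassium channel Kcnt2 (-3.87), Trim15 (-3.50) and D130051D11Rik (-3.29) were lower too. No list passed, the smallest adjusted p being 0.424 for housekeeping genes (mean 0.83). The sarcomere list differed by -0.21 (adjusted p = 0.888), with Myh6 at -1.52 (adjusted p = 0.469), and the matrix list by -0.15 (adjusted p = 0.925), with fibronectin (Fn1) at 9.22 against 5.61 (adjusted p = 0.170). The mean 18S level was 10.5 in fibroTIPeR and 7.45 in fibroblast cells. With limma, 10 genes passed, 1 higher and 9 lower, all without overlap (3.57% of unselected genes by chance). With median centring 2 passed, 1 higher and 1 lower. With fibroTIPeR 1 to 3, the cells of high 18S level, 610 passed, 265 higher and 345 lower, whereas none passed with fibroTIPeR 4 and 5 alone or with the 18S level as a covariate. Without fibroTIPeR 3 none passed, and without fibroTIPeR 1, 2 or 5 there were 3, 1 and 72, without fibroblast 2 there were 16 and without fibroblast 3 there were 3. None of the 9 named genes passed without each cell in turn, and a probe set of Nfkbiz differed in sign from the one reported.

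Fibroblasts given fibroblast RNA were compared with untreated ones to show what transfection with RNA of their own kind went with. In the main fit of all cells, this comparison had more genes past the threshold than either comparison of the fibroTIPeR cells with a fibroblast control. That order did not hold in every fit. With the 18S level as a covariate, 0 passed in fibroControl against fibroblast and 3 in fibroTIPeR against fibroControl. With fibroTIPeR 1 to 3 alone, 610 genes passed in fibroTIPeR against fibroblast. The genes of fibroControl against fibroblast were not counted in that fit, so the order in it is not known. The largest measured rises, from levels below the median of all genes, were in Pglyrp2, which degrades bacterial peptidoglycan, at 12.65 ± 0.34 (SD, n = 3) against 3.41 ± 1.11 (n = 3; adjusted p = 0.00872), gastric lipase (Lipf, 7.87), angiogenin (Ang, 7.54), the nucleolar protein Noc4l (7.52), Arhgap18 (7.16), Fth1 (7.14, adjusted p = 0.00512), Gtf2ird2 (6.53) and the mitotic kinase Melk (6.43). The largest falls were in Naca, a chaperone of nascent proteins, at 4.44 ± 1.25 against 11.92 ± 2.22 (adjusted p = 0.00872), Carnmt1 (-7.44), Rfc3 (-6.69), Dnajc21 (-6.54), the DNA sensor Aim2 (-6.50), 1500004A13Rik (-6.33), Parp14 (-6.32) and the granzyme Gzmd (-6.08).

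Of 31 matrix genes, Mmp2 (5.48, SE 1.17, adjusted p = 0.0193) and Col6a3 (3.94, adjusted p = 0.0357) rose in fibroControl cells and 29 did not pass, while 3 rose adjusted over the list alone; the list mean was 0.87 (adjusted p = 0.163). In the calcium list triadin (Trdn), which anchors the calcium release complex, fell (-4.80, SE 0.92, adjusted p = 0.0140) and 25 did not pass (mean -0.80, adjusted p = 0.163). Other list members past the threshold were the protease inhibitor Cst3 (4.36), the neuronal enolase Eno2 (2.74) and Hspa1a (4.28) among those that rose, and the myogenic factor Myf6 (-4.93) and the cell cycle gene Cdc20 (-0.94, which turned to 0.18 with the mean of its probe sets) among those that fell. Laptm5 was 0.33 higher, which turned to -0.30 with the mean of its probe sets. No list passed; the smallest adjusted p was 0.163, shared by the calcium, matrix, oligodendrocyte (mean -0.996) and housekeeping (mean 1.30) lists. The interferon and foreign RNA list had a mean of -0.10 (adjusted p = 0.775). The 18S level was 11.6 in fibroControl and 7.45 in fibroblast cells, with no overlap.

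Between fibroControl and fibroblast cells, 283 genes passed with limma, 131 higher and 152 lower. In 281 of them the groups did not overlap, which selection by the threshold favours (10% of unselected genes would do so by chance). Median centring gave 143, of which 82 were higher. Leaving out fibroControl 1, 2 or 3 gave 85, 134 and 144, and leaving out fibroblast 1, 2 or 3 gave 134, 42 and 67; 9 of 25 named genes passed without each cell in turn, namely Arhgap18, Carnmt1, Dnajc21, Fth1, Lipf, Naca, Noc4l, Pglyrp2 and Rfc3. With the 18S level, which did not overlap between the groups, as a covariate no gene passed; over the 283 genes the median difference in size went from 3.73 (median SE 0.87) to 2.64 (median SE 1.10), in the same direction for all 283. Another probe set of Ang, Noc4l, Arhgap18, Carnmt1, Dnajc21 and 1500004A13Rik differed in sign, in Ang for 2 of 3 probe sets.

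FibroTIPeR cells were set against cardiomyocytes to show what still parted them from the donor type. Several sarcomere genes were lower in fibroTIPeR cells. Myl2 was at 3.31 ± 0.69 (SD, n = 5) against 9.90 ± 0.88 (n = 4; adjusted p = 2.19e-07), Tnni3 at 5.05 ± 1.15 against 11.96 ± 0.98 (adjusted p = 2.17e-06) and Myh6 at 5.09 ± 0.36 against 10.91 ± 0.89 (adjusted p = 5.83e-06). Plin5 (-5.76), Myoz2 (-5.12), the calcium pump regulator phospholamban (Pln, -4.24), Lpl (-4.23) and nebulette (Nebl, -4.08) fell too. Vim was at 13.96 ± 0.68 against 5.81 ± 3.77 (adjusted p = 3.33e-05) and Cald1 was 7.56 higher (adjusted p = 2.17e-06). Further rises were in the protease inhibitor Timp2 (6.97), the membrane glycoprotein podoplanin (Pdpn, 6.76), the elongation factor Eef1a1 (6.63), Actn1 (6.57), the kinetochore gene Zwint (6.46) and Tuba1a (6.33).

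In this comparison 7 of 25 sarcomere genes fell and 18 did not pass (11 lower adjusted over the list alone), with a list mean of -2.05 (SE over genes 0.45, adjusted p = 1.12e-11). Calcium handling fell by 1.03 (adjusted p = 0.00144), with Pln and Ryr2 (-3.65) lower and 24 not passing (5 lower adjusted over the list alone). Energy metabolism fell by 1.18 (adjusted p = 5.01e-05), with 5 of 21 lower over all genes and also adjusted over the list alone, among them Lpl, Cox7a1 (-3.50), the fatty acid carrier Cd36 (-3.34) and Ckmt2 (-3.02). Matrix genes rose by 1.24 (SE 0.41, adjusted p = 0.000275), with Vim, Col1a2 (5.11), S100a4 (4.96) and Fn1 (3.64) higher and 27 not passing (6 higher adjusted over the list alone). Housekeeping genes rose by 2.45 (SE 0.66, adjusted p = 5.82e-08, and adjusted p = 0.0751 with an estimated correlation); Eef1a1, Actb (5.69) and Rps18 (3.69) were higher and 10 did not pass, while 8 were higher and 1 lower adjusted over the list alone. The 18S level in these groups was 10.5 and 7.48. Cardiac transcription factors had a mean of -0.40 (adjusted p = 0.348) with none of 22 past the threshold, and Tnnt2 (-0.94), Nppa (1.10) and Gata4 (0.30) did not pass. Smooth muscle genes had a mean of 1.505 (adjusted p = 0.0920) with Cald1 higher.

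Of 18193 genes, 102 passed between fibroTIPeR and cardiomyocyte cells with limma, 77 higher and 25 lower. Of these, 89 were without overlap (1.59% of unselected genes by chance). The median of all genes was -0.14, and -0.24 in the values as deposited and -0.034 with median centring. The balance of directions differed between fits: with the 18S level as a covariate 12 genes passed, 2 higher and 10 lower, with fibroTIPeR 4 and 5 alone 9 passed, 3 higher and 6 lower, and with fibroTIPeR 1 to 3 alone 1056 passed, 627 higher and 429 lower. Leaving out fibroTIPeR 1, 3, 4 or 5 gave 40, 41, 216 and 269 genes, and leaving out cardiomyocyte 1, 2 or 3 gave 54, 58 and 44; 16 of 25 named genes passed without each cell in turn, Myh6, Myl2, Tnni3, Myoz2, Vim and Cald1 among them. Another probe set of Cald1, Timp2, Zwint, Plin5, Lpl and Nebl differed in sign.

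AstroTIPeR and astroControl cells were compared to ask what RNA of cardiomyocytes did in astrocytes. The ciliary transport gene Ift88 was at 10.11 ± 0.41 (SD, n = 6) against 5.85 ± 0.40 (n = 2), a rise of 4.26 (SE 0.75, adjusted p = 0.0180), and Dnm1, a dynamin of synaptic vesicle uptake, rose by 3.49 (adjusted p = 0.0174). The hyaluronidase Hyal5 fell by 5.31 (SE 0.75, adjusted p = 0.00279), the unconventional myosin Myo3a by 5.51, Lrrn1 by 4.91, the collagen Col19a1 by 4.45, Ms4a3 by 4.34, the carbonic anhydrase Car13 by 4.34 and Gm14169 by 3.82. None of these belongs to a fixed list, and no list passed. The Gapdh 3' to 5' difference parted these groups without overlap, at 2.94 to 5.05 in astroTIPeR and 1.51 and 2.63 in astroControl cells. The sarcomere list had a mean of -0.25 (adjusted p = 0.436), with the muscle filament desmin (Des) at 5.58 ± 0.66 against 9.06 ± 1.26 (adjusted p = 0.212). Calcium handling had a mean of 0.42 and cardiac transcription factors 0.40 (both adjusted p = 0.368). Astrocyte genes had a mean of 0.60 (adjusted p = 0.368), with the lipid enzyme Acsbg1 at 8.40 against 5.33. In the matrix list (mean 0.34, adjusted p = 0.419), 2 members were higher adjusted over the list alone, and the growth factor receptor Pdgfrb was at 11.997 ± 0.47 against 9.47 ± 0.09 (adjusted p = 0.103).

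With limma, 9 genes passed between astroTIPeR and astroControl cells, 2 higher and 7 lower, all without overlap (7.14% of unselected genes by chance). The number depended on the scaling. It was 72 in the values as deposited (27 higher), 68 with median centring (35 higher) and 87 with quantile normalization within each array set (30 higher), and each of these held the 9; the median of all genes was 0.079, and 0.20 with median centring. Without astroTIPeR 5 there were 4 genes, without astroControl 2 there were 5 and without astroControl 1 there were 543, where the lone astroControl cell is assumed to vary like the other groups. Hyal5 was the 1 gene of 9 that passed without each cell in turn. Another probe set of Dnm1, Lrrn1 and Col19a1 differed in sign.

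AstroTIPeR cells were set against cardiomyocytes, a comparison that crosses the 2 array sets, so that array set and cell type cannot be told apart in it. Tnni3 was at 4.46 ± 0.29 (SD, n = 6) against 11.96 ± 0.98 (n = 4; adjusted p = 2.28e-07), Myl2 fell by 6.44 (adjusted p = 1.54e-07), Myh6 by 6.25 (adjusted p = 7.44e-07), Plin5 by 5.77, Atp2a2 by 5.44, Carnmt1 by 5.43, Myoz2 by 5.29 and Naca by 4.74. Ang (9.26), the signalling gene Rasal3 (8.51), Pglyrp2 (8.50), Lipf (8.07), Bex1 (7.57), the inflammasome adaptor Pycard (7.50), Arhgap18 (7.45) and Tlcd4 (7.01) rose most. Of the sarcomere genes 10 of 25 fell, Actc1 (-4.01) and Tnnt2 (-3.52) included, and 15 did not pass (11 lower adjusted over the list alone); the list mean was -2.28 (SE over genes 0.48, adjusted p = 1.19e-14). Energy metabolism fell by 0.91 (adjusted p = 0.00125), with Cox7a1 (-4.34), Pfkm (-2.87), Ckmt2 (-2.17) and Mb (-1.90) lower and 17 not passing (6 lower adjusted over the list alone). Calcium handling fell by 0.77 (adjusted p = 0.0346, and adjusted p = 0.160 with an estimated correlation), with Atp2a2, Trdn (-4.04), Ryr2 (-3.40) and Srl (-3.11) lower and 22 not passing (5 lower and 1 higher adjusted over the list alone).

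Housekeeping genes rose by 1.45 against cardiomyocytes (adjusted p = 0.00476, and adjusted p = 0.312 with an estimated correlation), with Eef1a1 (4.91) and Actb (4.90) higher and 11 not passing, and 2 higher adjusted over the list alone. Macrophage and microglia genes rose by 1.01 (adjusted p = 0.0336, and adjusted p = 0.296 with an estimated correlation), with lysozyme (Lyz2, 3.96, adjusted p = 0.0498) higher and 13 not passing (3 higher and 1 lower adjusted over the list alone). Matrix genes had a mean of 0.70 (adjusted p = 0.0843), where Vim (6.64) was higher and periostin (Postn, -4.21) lower. Cald1 (6.84), the replication helicase gene Mcm5 (4.75) and Hspa1a (5.05) rose as well. Astrocyte genes had a mean of 0.19 (adjusted p = 0.949), and Gfap differed by -1.44 (adjusted p = 0.310). The 18S level was 8.73 in astroTIPeR and 7.48 in cardiomyocyte cells.

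Between astroTIPeR and cardiomyocyte cells 387 genes passed with limma, 253 higher and 134 lower. Of these, 333 were without overlap (0.952% of unselected genes by chance). The share of higher genes differed between scalings. The values as deposited gave 3984 genes, 462 higher and 3522 lower, quantile normalization within each set 3282, 440 of them higher, and median centring 2620, 2239 of them higher; 328, 330 and 383 of the 387 were among them. The median of all genes moved from -0.0071 to -0.80 in the values as deposited, -0.70 within sets and 0.33 with median centring. The calcium list did not pass with any of these 3 scalings (adjusted p = 0.08004, 0.103 and 0.0672), and energy metabolism (0.111) and macrophage genes (0.0757) did not pass with median centring. Without cardiomyocyte 2 there were 217 genes, and 27 of 33 named genes passed without each cell in turn. The calcium list did not pass without cardiomyocytes 3 (0.0878) or 4 (0.0605) or astroTIPeR 6 (0.0708), the macrophage list without cardiomyocyte 1 (0.0909) or astroTIPeR 4 (0.0945), 5 (0.0535) or 6 (0.0798), and the housekeeping list without cardiomyocyte 1 (0.0521). Another probe set of Ang, Pycard, Tlcd4, Plin5, Atp2a2 and Carnmt1 differed in sign, in Ang and Pycard for 2 of 3 probe sets and in Tlcd4 for 2 of 4.

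The genes that parted cardiomyocytes from fibroblasts were followed through the treated cells. Of the 18 higher in cardiomyocytes, none passed in fibroTIPeR against fibroControl cells (median -0.062, 6 positive) or in astroTIPeR against astroControl cells (median 0.18, 9 positive). In contrast, 14 of them fell in fibroTIPeR against cardiomyocyte cells (median -3.67) and 14 in astroTIPeR against cardiomyocyte cells (median -3.38). Of the 23 lower in cardiomyocytes, none passed in either comparison with a control (medians 0.084 and 0.35), 17 were higher in fibroTIPeR than in cardiomyocyte cells (median 4.83) and 9 in astroTIPeR than in cardiomyocyte cells (median 3.05). These counts share their cardiomyocytes with the choice of genes, so the comparisons with cardiomyocytes are not independent of it.

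A position between the reference types was computed for each cell from the 100 genes highest and the 100 lowest in cardiomyocytes over fibroblasts. The fibroblast mean was set at 0 and the cardiomyocyte mean at 1. The same fibroblasts and cardiomyocytes chose the genes and set the scale, so cells outside this choice tend to lie between. A position between 0 and 1 is therefore not by itself a move toward cardiomyocytes, and treated cells are read against their controls. FibroTIPeR cells lay at 0.232 ± 0.283 (SD, n = 5), from -0.177 in replicate 1 to 0.5262 in replicate 2, and fibroControl cells at 0.232 ± 0.00934 (n = 3). The difference was -0.000239 (two-sided exact permutation p = 0.964 over 56 splits, interval -0.415 to 0.3, smallest p possible 0.0357). AstroTIPeR cells lay at 0.465 ± 0.134 (n = 6) and astroControl cells at 0.454 ± 0.0393 (n = 2), a difference of 0.0107 (two-sided exact permutation p = 0.714); with 28 splits the smallest p possible is 0.0714, so that this comparison could not pass 0.05. Levels of astrocytes on this axis cross the 2 array sets. With the fixed cardiac and fibroblast lists as the axis, fibroTIPeR cells lay at -0.0019 and fibroControl cells at -0.498 (difference 0.496, exact permutation p = 0.143), and astroTIPeR and astroControl cells at 0.291 and 0.392 (difference -0.101, exact permutation p = 0.571).

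**Figure D3:**
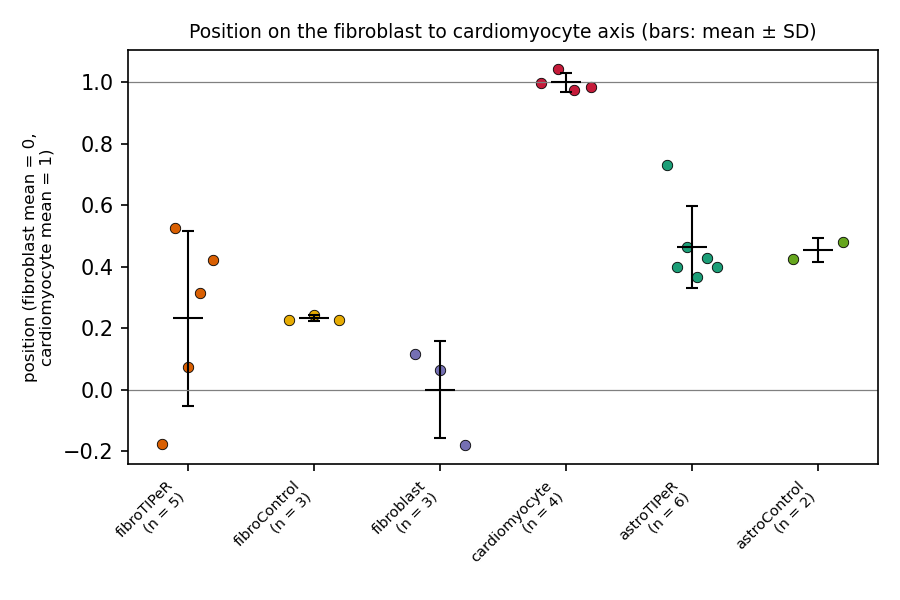
Position of every cell between fibroblasts (mean 0) and cardiomyocytes (mean 1), by group; dots are cells and bars the mean ± SD, on an axis without unit. FibroTIPeR cells average 0.232, like the fibroControl cells, and astroTIPeR cells 0.465, against 0.454 in astroControl cells. Because fibroblasts and cardiomyocytes chose the axis genes, a position between 0 and 1 in another group need not mean a move toward cardiomyocytes.

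Across all 18193 genes, the differences between fibroTIPeR and fibroControl cells were set against those between cardiomyocytes and fibroblasts, with r = -0.0278 (exact permutation p = 0.893). The astroTIPeR differences gave r = -0.00192 with the same reference (exact permutation p = 0.643, where 28 splits allow no p under 0.0714), and the fibroTIPeR and astroTIPeR differences gave r = 0.0725 with each other (exact permutation p = 0.393). Genes are not independent replicates, so the cells were permuted; 3 correlations were computed, and the Benjamini-Hochberg adjusted p was 0.893 for each.

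The difference of the transfer effect between the recipient types was tested as an interaction, in which the controls differ in kind, fibroblast RNA in the one and a mock transfection in the other. No gene passed with limma, 1392 had an unadjusted p under 0.05 and the smallest adjusted p was 0.166. The 5 genes with the smallest p were Hyal5 (5.46, SE 1.01), Fancl (-4.78), Ift88 (-4.96), Nxph2 (4.88) and D6Ertd527e (4.51). Without astroControl 1, 237 genes passed, where the lone astroControl cell is assumed to vary like the other groups. The fibroblast and extracellular matrix list fell by 1.36 on average (SE over genes 0.36, adjusted p = 0.0128, and adjusted p = 0.473 with an estimated correlation), with none of 31 members past the threshold and 3 lower adjusted over the list alone, Mmp2 having the smallest p (-6.73, adjusted p = 0.298). The list did not pass without fibroControl 2 (0.208), fibroControl 3 (0.132), astroControl 1 (0.0817) or astroControl 2 (0.0839). The other lists had adjusted p from 0.349 to 0.857, with 0.390 for the sarcomere (mean 0.46).

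In 29 of the 136 tests of a list in a comparison, mean, median and test differed in sign, and none of these 29 passed. Between cardiomyocytes and fibroblasts this held for the oligodendrocyte, endothelial, cell cycle and interferon lists. Between fibroTIPeR and fibroControl cells it held for the cardiac transcription factor, astrocyte and interferon lists, between fibroTIPeR and fibroblast cells for the sarcomere, cardiac transcription factor, energy, neuron, macrophage, interferon and stress lists, and between fibroControl and fibroblast cells for the cardiac transcription factor, energy, skeletal muscle, neuron, macrophage and cell cycle lists. It held for skeletal muscle between fibroTIPeR and cardiomyocyte cells, for neuron and oligodendrocyte between astroTIPeR and astroControl cells, for skeletal muscle, astrocyte, endothelial and cell cycle between astroTIPeR and cardiomyocyte cells, and for calcium handling and energy in the difference of effects.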

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

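The tests of the 18S level, of RNA transfection and of a library batch in the first pattern, of a single control cell and of the 18S level in the second, and of cardiomyocyte RNA in the third were chosen only after the result was seen. Chance gives about 1 outlying cell in 20 groups, and 5 were found in 78 groups tested, where 3.9 are expected.

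The mean level of the 18S control probe sets, which no comparison used, was 11.6 in fibroControl and 10.5 in fibroTIPeR cells, above the fibroblasts at 7.05 to 8.06, and this parting of the libraries went with the 283 genes that differed between fibroControl and fibroblast cells (highest other split 36; 10 splits are too few for a share under 0.05). Within the 6 astroTIPeR cells a score of these genes had r = 0.688 with the 18S level (exact permutation p = 0.131; rho = 0.714, exact permutation p = 0.136; r = 0.804 without the 2 cells farthest from the median), which leaves the ribosomal and repeat RNA content of the libraries open as an explanation. RNA transfection itself, the biological explanation that the design gives, stays open because RNA uptake was not measured in single cells; 0 of the 5 fibroTIPeR cells scored under 0.25, which decides nothing, as left-out fibroblasts reached 0.263 and 0.256 and cardiomyocytes 0.347, but fibroTIPeR 4 and 5, which were given RNA, scored 0.361 and 0.263, near these and below left-out fibroControl cells (0.643 to 0.683), and mock-transfected astroControl cells, across the array sets, scored 0.687 and 0.610. Each left-out score rests on genes called anew without that cell and is scaled on the remaining cells. Such scores and those from the 283 genes are therefore not on the same scale, and close matches between them carry no weight. In 40.3% of the 283 genes fibroTIPeR 1 to 3 all lay on the fibroControl side of fibroTIPeR 4 and 5. Any other way to part 3 from 2 gave at most 13.4%, and chance would give 10%. A library batch that the labels do not give may underlie the pattern, and these 3 cells scored 0.635 to 0.753. Over all genes the cells did not part this way. On the first principal component fibroTIPeR 2 lay at -12.3, nearer to cells 4 and 5 (-39.7 and -49.4) than to cells 1 and 3 (191 and 120). However, fibroTIPeR 1 to 3 were also the cells of high 18S level (11.03 to 13.5, against 7.80 and 7.88). The parting therefore cannot tell such a batch from the 18S content of the libraries. The test of RNA transfection first rested on the bound of 0.25 alone, which the cells met. A condition on the distance below the left-out fibroControl cells, which left it undecided, was added after its values were seen. The condition as set down in words differed from it. It asked that fibroTIPeR cells score like left-out fibroControl cells, with at most 1 cell at or below the highest left-out fibroblast. The bound on fibroblasts was met, with fibroTIPeR 5 as that cell, but fibroTIPeR 4, at 0.361, did not score like the fibroControl cells. The verdict therefore depends on which condition is used.

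The fibroblast and extracellular matrix list was lower in fibroTIPeR than in fibroControl cells (adjusted p = 0.00350, and adjusted p = 0.287 with an estimated correlation), and among lists and genes it gave the one difference between recipient types past the threshold, -1.36 (adjusted p = 0.0128, and adjusted p = 0.473 with an estimated correlation). Chance cannot be excluded, since 4 of 56 splits of the 8 cells gave a list p as small in the same direction as the real 0.000206, the smallest being 1.54e-05. A difference in 18S content is argued against as the whole cause, because the list mean was alike at high and low 18S levels. The list mean was -1.03 (SE over genes 0.287, 23 of 31 members lower, camera adjusted p = 0.0112) in fibroTIPeR 1 to 3. Their 18S levels of 12.4, 11.03 and 13.5 were high like the controls, though outside the control range of 11.2 to 12.1. In fibroTIPeR 4 and 5, at 7.80 and 7.88, the list mean was -1.01 (SE 0.378, 20 of 31 lower), but the list did not pass (camera adjusted p = 0.0885). The call may rest on single control cells, as the adjusted p was 0.277 without fibroControl 3 (list mean -0.73), 0.161 without fibroControl 2 (-0.77) and 7.45e-07 without fibroControl 1 (-1.57), although the mean was negative each time. An effect of cardiomyocyte RNA on matrix genes, the biological explanation that the design gives, stays open, while the list mean was -0.15 (adjusted p = 0.925) between fibroTIPeR and untreated fibroblast cells, whose levels were 8.02 and 8.17 against 9.04 in fibroControl cells.

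Fibroblast 3 stood apart from the other two fibroblasts, with Tnnt2 at 11.28 and Myh6 at 8.48. Cardiomyocyte RNA in that library could have been the source, and Myh6 would imply a share of 18.6%. Over 6 other sarcomere genes, however, the observed level lay below the level implied by that share by a median difference of -2.57 (quartiles -4.30 and -1.45), in all 6, which argues against it. No biological explanation was tested.

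In fibroTIPeR against fibroControl, 21 of 56 splits gave as many genes as the real 1, so chance cannot be excluded; the highest other split gave 527 and set fibroTIPeR 1 and 3 with the fibroControl cells, which points to a structure of the samples. In fibroTIPeR against fibroblast, 8 of 56 splits gave as many as the real 10, so chance cannot be excluded there either, and the highest other split, with 2328, set fibroTIPeR 2, 4 and 5 with fibroblasts 1 and 2, again a structure of the samples. For cardiomyocyte against fibroblast, 1 of 35 splits, the real one, gave 41 genes (highest other 28), and 1 of 35 gave 6 lists (highest other 5). Where TIPeR cells were set against cardiomyocytes, the 100 splits were the real one and others drawn at random, not all that are possible. A split that was not drawn may have given more genes or lists. For fibroTIPeR against cardiomyocyte, 2 of 100 splits gave 102 genes or more (highest other 135), and 2 of 100 gave 5 lists (highest other 5). For astroTIPeR against cardiomyocyte, 1 of 100 gave 387 genes (highest other 7), and 3 of 100 gave 5 lists or more (highest other 6). These shares are under 0.05 but not adjusted over the comparisons, so chance is made unlikely for these cells without being excluded. In astroTIPeR against cardiomyocyte the array set parts the groups as well.

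AstroTIPeR 1 lay far from its group in position, at 0.729 against 0.365 to 0.465, and in Col1a1, at 5.52 against 7.37 to 8.49. Cardiomyocyte 1 was low in Ryr2, at 6.44 against 8.02 to 8.26. FibroTIPeR 1 was low in the glutamate transporter Slc1a3, at 7.32 against 10.30 to 10.998. AstroTIPeR 5 had a mean level of the sarcomere list of 5.15, against 5.44 to 5.60.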

How the results depend on the processing

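The alternatives with the 18S level, quantile normalization within each array set, and fibroTIPeR cells split by replicate were chosen after seeing the data. No pseudocount alternative was run, since the values are log2. Of 123 named gene results that passed, 3 reversed in sign, all with the mean of all probe sets. Laptm5 turned to -0.14 in cardiomyocyte against fibroblast and to -0.30 in fibroControl against fibroblast, and Cdc20 to 0.18 in fibroControl against fibroblast. None of 18 list results reversed in sign. Results that kept their sign but no longer passed are not counted as reversed. The lists that passed fell from 18 to 9 with an estimated correlation. Where counts of genes moved, the cause was not tested, except that fits of fewer cells or groups rest on fewer cells.

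For cardiomyocyte against fibroblast the count of 41 became 21 in the values as deposited, 18 with median centring, 18 with the mean of probe sets, 21 without trend, 1130 with arrayWeights, 2 with the compared groups alone and 71 with the 18S level as a covariate, and 11 to 37 with a cell left out. For fibroTIPeR against fibroControl the count of 1 became 0 with genes above the median level, 3 with the mean of probe sets, 2 without trend, 0 with the compared groups alone, 3 with the 18S level, 0 with fibroTIPeR 1 to 3 and 161 with fibroTIPeR 4 and 5, and 1 to 17 with a cell left out. For fibroTIPeR against fibroblast the count of 10 became 2 with median centring, 1 with the level filter, 3 with the mean of probe sets, 2 with every probe set, 1 without trend, 49 with arrayWeights, 0 with the compared groups alone, 0 with the 18S level, 2 within sets, 610 with fibroTIPeR 1 to 3 and 0 with fibroTIPeR 4 and 5, and 0 to 72 with a cell left out. For fibroControl against fibroblast the count of 283 became 135 as deposited, 143 with centring, 173 with the filter, 596 with every probe set, 1890 with arrayWeights, 86 with the compared groups alone, 0 with the 18S level and 156 within sets, and 42 to 144 with a cell left out.

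For fibroTIPeR against cardiomyocyte the count of 102 became 63 with centring, 252 with every probe set, 30 with the compared groups alone, 12 with the 18S level, 1056 with fibroTIPeR 1 to 3 (100 of the 102 among them) and 9 with fibroTIPeR 4 and 5, and 40 to 269 with a cell left out. For astroTIPeR against astroControl the count of 9 became 72 as deposited, 68 with centring, 4 with the filter, 5 with the mean of probe sets, 57 with every probe set, 1 with arrayWeights, 20 with the 18S level and 87 within sets, and 4 to 543 with a cell left out. For astroTIPeR against cardiomyocyte the count of 387 became 3984 as deposited, 2620 with centring, 841 with every probe set, 1781 with arrayWeights, 888 with the compared groups alone and 3282 within sets, and 217 to 392 with a cell left out. The count of 0 for the difference of effects became 2 with the mean of probe sets, 1 within sets and 24 with fibroTIPeR 4 and 5, and 0 to 237 with a cell left out. A left-out astroControl cell leaves a lone sample that is assumed to vary like the other groups.

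The difference in position of fibroTIPeR cells changed sign from -0.000239 to 0.00405 as deposited, 0.0138 with the filter, 0.496 with the fixed lists, 0.00228 within sets and 0.136 with fibroTIPeR 4 and 5, and ran from -0.0886 to 0.102 with a cell left out. That of astroTIPeR cells changed from 0.0107 to -0.0311 with 50 genes, -0.00992 with 500, -0.0162 as deposited, -0.101 with the fixed lists and -0.0150 with the 18S level, and ran from -0.0476 to 0.0384. None of these passed. The first correlation became 0.0189 with the filter and 0.110 over genes past the threshold in the reference, with -0.117 to 0.0708 when a cell was left out, and the second became 0.00967 with Spearman and 0.00303 with the filter, with -0.0389 to 0.0219; the third kept its sign throughout, with 0.0264 to 0.106 when a cell was left out. Within-group agreement with Spearman was 0.697 in fibroTIPeR, 0.725 in fibroControl, 0.794 in fibroblast, 0.756 in cardiomyocyte, 0.80 in astroTIPeR and 0.624 in astroControl cells, and with the filter 0.675 in fibroTIPeR, 0.767 in fibroControl, 0.753 in fibroblast, 0.840 in astroTIPeR and 0.736 in astroControl cells.

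Replicates of different groups share only a number, and no comparison had every pair of equal numbers correlated above 0.1 (pair correlations from -0.341 to 0.285). With the replicate number as a block the counts were 29, 1, 9, 163, 111, 3 and 330 in the 7 comparisons and 0 in the difference of effects, and the difference in position of fibroTIPeR cells was 0.0454. With the block, calcium handling (adjusted p = 0.0995) and smooth muscle genes (0.0597) did not pass in cardiomyocyte against fibroblast, nor calcium handling (0.0791) and macrophage genes (0.0876) in astroTIPeR against cardiomyocyte.

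Apart from the block, an estimated correlation, scalings and left-out cells, list calls ended under the following settings, as adjusted p. In cardiomyocyte against fibroblast, calcium handling gave 0.0762 with the filter and 0.0505 with fibroTIPeR 1 to 3 in the fit, energy metabolism 0.322 with the filter and housekeeping 0.216 with fry. The matrix list gave 0.187 with fry and 0.0885 with fibroTIPeR 4 and 5 in fibroTIPeR against fibroControl, and 0.3003, 0.0793 and, with the filter, 0.130 in the difference of effects. Against cardiomyocytes, housekeeping gave 0.0596 in fibroTIPeR and 0.115 in astroTIPeR cells with the 18S level, and in astroTIPeR cells 0.135 with fry; calcium handling gave 0.0673 with the filter and 0.107 with the 18S level there, and macrophage genes 0.0751 with fry and 0.174 with the filter. The sarcomere list passed under all settings run in the 3 comparisons where it was called, as did the matrix list in cardiomyocyte against fibroblast and the calcium, energy and matrix lists in fibroTIPeR against cardiomyocyte.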

Other observations

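Genes that moved together in comparisons with no cell in common were compared after their values were seen. Of 131 genes higher in fibroControl than in fibroblast cells and 253 higher in astroTIPeR than in cardiomyocyte cells, 31 were shared. If the lists were independent, 1.82 are expected. Of 152 and 134 lower, 13 were shared, where 1.12 are expected, and 0 genes went opposite ways. Both comparisons came from 1 fit that shares the spread of each gene, so the expected counts may be too low. In both, the first group had the higher mean 18S level (11.6 against 7.45, and 8.73 against 7.48). Pglyrp2, a peptidoglycan amidase, was at 12.65 ± 0.34 (SD, n = 3) in fibroControl, 12.97 ± 0.29 (n = 6) in astroTIPeR and 12.63 ± 0.24 (n = 2) in mock-transfected astroControl cells, but at 3.41 ± 1.11 (n = 3) in fibroblast and 4.47 ± 0.75 (n = 4) in cardiomyocyte cells. In fibroTIPeR cells 1 to 5 it was at 9.08, 13.32, 10.13, 3.56 and 4.38, whereas Fth1 was at 12.58, 10.33, 11.96, 6.98 and 10.57 and Carnmt1 at 7.05, 10.09, 5.49, 7.96 and 9.80, so that Fth1 and Carnmt1 did not part cells 1 to 3 from cells 4 and 5. Lipf, Ang and Arhgap18 had means of 11.63, 11.13 and 11.64 in fibroControl and 12.74, 12.50 and 12.02 in astroTIPeR cells, against 3.75, 3.58 and 4.48 in fibroblasts. Fth1 was at 11.68 in fibroControl, 10.30 in astroTIPeR and 4.55 in fibroblast cells. Carnmt1 ran the other way, at 5.86 in fibroControl, 5.85 in astroTIPeR, 13.30 in fibroblast and 11.28 in cardiomyocyte cells. Each level is that of 1 probe set. In both comparisons 2 of 3 probe sets of Ang and 1 of 2 of Carnmt1 differed in sign from the one used. For Arhgap18, 1 of 2 did so in fibroControl against fibroblast. The levels of astrocytes cross the 2 array sets.

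Gfap averaged 4.69 in astroTIPeR and 5.32 in astroControl cells, below 6.01 in fibroblasts and 6.13 in cardiomyocytes, and the water channel Aqp4 averaged 5.70 and 6.21, against 6.82 and 5.92. Slc1a3 was high in every group, with means from 9.95 in astroControl to 10.79 in cardiomyocyte cells. These levels were not tested between astrocytes and fibroblasts, and they cross the 2 array sets.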
